A study of Mus musculus with 4 samples.

How the data were processed

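Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA. Per the labels, green fluorescent mesenchymal cells were sorted from the palate of mouse embryos at E14.5, and 50000 cells were pooled for each group. The labels give 2 control libraries (Shox2Cre/+;Nkx2.5F/F;R26RmTmG) and 2 mutant libraries (Shox2Cre/-;Nkx2.5F/F;R26RmTmG), and samples were grouped by those genotypes. The labels do not say whether libraries of a group came from separate pools of embryos, so every spread between them may be technical.

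The authors deposited 1 peak list per library, without a header, in the 10 columns of the narrowPeak layout. Coordinates were in mm10, per the submitters' processing notes. The aligner, the treatment of the transposase offset, the peak caller and its settings are not given in the sources used here. The deposited score of a peak was the whole part of 10 times its −log10 p in all rows of control 1 and mutant 2, in 22963 of the 22966 rows of control 2 and in 29223 of the 29225 rows of mutant 1. The deposited enrichment column was read as a fold enrichment from its values and its place in the layout of the authors' files, which defines it only as overall enrichment, and the background it is relative to is not given in the sources used here. The deposited −log10 p-value and −log10 q-value likewise belong to single peaks. These values are the authors' own and were used only to rank, filter or describe peaks within a library. The peak numbers in the deposited names ran to 108634 in control 1, 96525 in control 2, 113404 in mutant 1 and 119417 in mutant 2, while 27.8%, 23.8%, 25.8% and 26.7% of the numbered peaks were listed. Peaks were therefore taken out after numbering, by a step not given in the sources used here. Read depth is unknown, so no counting error could be attached to a peak.

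Peaks on chromosomes 1 to 19 and X were merged across the 4 libraries where they shared at least 1 bp, and each merged interval is called a region. A region was control-only when both control libraries and no mutant library held a peak in it, and mutant-only in the reverse case. Presence of a call was compared, since peak lists hold no read counts. Library similarity was the Jaccard index over base pairs for the 6 pairs of libraries. The 4 libraries can be paired in 3 ways, so an exact test over pairings cannot give a p under 0.333.

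The gene table used was of the GRCm38.p6 assembly, the same build as mm10, and gave gene starts and ends without strand. Regions were described by their midpoint, as within 1 kb of either end of a protein-coding gene, inside a gene, or outside genes. They were assigned to the nearest of 21631 protein-coding genes within 100 kb. The plan had named transcription start sites, exons and introns, which this table does not give. The plan also held 21 motifs, which were not analysed here because no genome sequence was used.

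Near-end shares of control-only and mutant-only regions were compared by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment, and intervals came from 10000 resamples of whole chromosomes. Regions are not independent replicates. For each of 22 gene lists, with 387 entries and 362 distinct genes, the mean per gene of control-only minus mutant-only regions was set against 10000 random lists. These were matched on the number of assigned regions in 10 bins, with a two-sided permutation p over genes, which covers the choice of genes and not the spread between embryos, and Benjamini-Hochberg adjustment over the lists. A two-sided Fisher's exact test per gene was planned for genes with at least 5 group-specific regions. The design, the lists, the other settings and the rule for named genes were fixed before the data were examined. The rule names Shox2 and Nkx2-5, the 10 genes per direction with the smallest Fisher p, up to 3 members per list whose region counts differ by at least 2, and the 5 control-only and 5 mutant-only regions with the highest lower percentile. The percentile of a peak is its rank by −log10 p within its own library, and the lower percentile of a region is the lowest over the libraries that hold it.

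Chosen after the data were seen were a yield-balanced ratio, an expected number of regions and a test of regions held by all 4 libraries. The ratio is the geometric mean of the 2 classes of a pairing over that of the 4 other classes of regions found in exactly 2 libraries, so that a difference in library yield cancels. The ratios of the 3 pairings multiply to 1 by construction. The expected number came from a Poisson fit with a term per library and one per number of libraries, to the 12 classes of 1 to 3 libraries outside the pairing tested. Intervals for both came from 2000 resamples of whole chromosomes. The third test compared regions in all 4 libraries per gene with 10000 random lists matched on the genomic territory of each gene.

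The other settings tried, as fixed beforehand, were the upper 50% of each list by −log10 p, equal numbers of top-ranked peaks (22959 per library), autosomes only, each library left out, no peak of the other genotype within 500 bp, 50% reciprocal overlap, assignment within 20 kb or 1 Mb, a gene-end distance of 3 kb, at least 3 group-specific regions per gene and a replicate block. Exclusion of chromosome 3, exclusion of chromosomes 3 and X, and a limit to regions whose peaks all lie above percentile 25 of the full lists were added later.

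The tests were tried on simulated data. With genotype labels shuffled over regions, the list test called 1 of 880 lists. With 15% of the regions of the palate mesenchyme transcription factor list set to control-only, it called that list in 40 of 40 simulations over 14712 genes. That list had 174 regions, of which 4 were control-only in the real data, so the planted change was far larger. Smaller changes and shorter lists were not simulated. The gene test called 110 of 200 genes in which 80% of the regions were set to control-only. Only 196 genes entered that simulated test and 0 of them were unchanged, so its false calls were not measured. Over 20 simulations the ratio averaged 0.994 where 1 was planted and 1.26 where 1.25 was planted. The change was planted by scaling the counts of the genotype classes themselves, so its recovery was fixed in advance. Libraries were drawn independently given the strength of a region and a yield per library. Removal of peaks and joint preparation of libraries were not simulated, so false excesses from these were not measured. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.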

Results

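ATAC-seq peak lists of sorted palatal mesenchyme at E14.5 were compared between 2 control and 2 mutant libraries. The series asks whether Shox2, a homeobox transcription factor of the anterior palate, is needed for chromatin accessibility in the Shox2 lineage. Cells carried a Cre inserted at Shox2 and a reporter that turns on green fluorescence after Cre acts. The controls kept 1 intact Shox2 allele, so the comparison is of 1 intact allele against none. Both genotypes were homozygous for a floxed allele of Nkx2-5, another homeobox gene. Cre can cut such an allele, so the controls were not wild type at Nkx2-5, and its loss in the sorted cells was not measured. The control lists held 30239 and 22966 peaks over 28.3 and 22.4 Mb, and the mutant lists 29225 and 31832 peaks over 27.4 and 30.0 Mb. Median peak widths were 876 and 924 bp in the controls and 880 and 881 bp in the mutants. The authors' median fold enrichment was 6.86 and 6.89 in the controls and 6.48 and 6.61 in the mutants.

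At Shox2 itself (mm10, chromosome 3, 66971723 to 66981771) 3 regions were assigned to the gene, and 0 of them lay within 1 kb of a gene end. The region inside the gene, at 66973378 to 66974132, held a peak in control 1, mutant 1 and mutant 2, with deposited fold enrichments of 4.99, 4.16 and 4.89. A region 17.9 kb outside the gene, at 66953472 to 66954241, was called in control 1 and mutant 2. A further one at 66882603 to 66883201, 88.8 kb away, was called in control 2. No region of Shox2 followed genotype, and the lists do not measure how much of the locus is left, so they do not check the genotype labels. At Nkx2-5 (chromosome 17, 26838664 to 26844988) a region at 26838593 to 26840423, over a gene end, held a peak in all 4 libraries. Its within-library percentiles were 25.5 and 35.2 in the controls and 60.5 and 60.5 in the mutants, and its deposited fold enrichments were 4.77 and 5.11 in the controls and 6.16 and 5.995 in the mutants. These are values of single peaks from 2 libraries per genotype, without read counts or a known read depth. Whether accessibility differed there cannot be read from them.

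**Figure D1:**
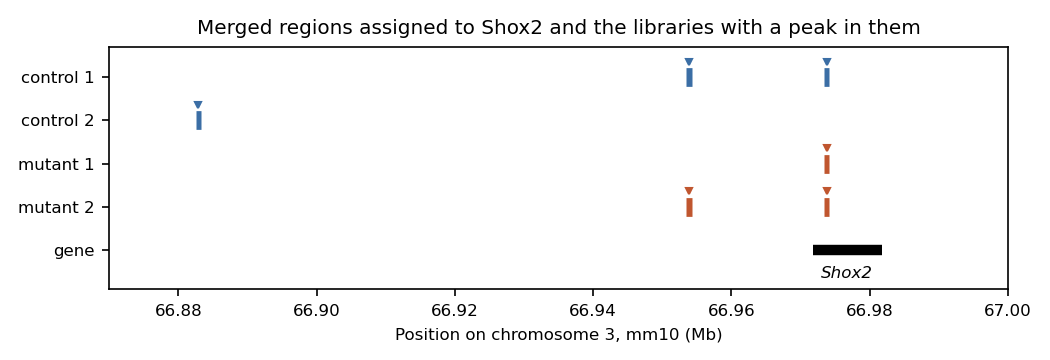
Positions on chromosome 3 (mm10, Mb) of the 3 regions assigned to Shox2, with a bar and triangle in the row of each library that holds a peak there and the gene as a black bar. The region inside the gene is marked in control 1, mutant 1 and mutant 2.

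Merging the 4 lists gave 39843 regions, of which 18904 held a peak in every library. Control-only regions numbered 425 and mutant-only regions 1782, a ratio of 4.19. The strongest control-only regions lay at the end of Mthfsl (chromosome 9, 88719849 to 88720721), 71.3 kb from Acpp, an acid phosphatase gene (chromosome 9, 104408662 to 104409350), and inside Taf4b, which encodes a subunit of the transcription factor TFIID (chromosome 18, 14889950 to 14890637). The next were 28.2 kb from Tfpi, a coagulation inhibitor gene (chromosome 2, 84504517 to 84505454), and 1.51 kb from Xdh, the xanthine dehydrogenase gene (chromosome 17, 73882093 to 73882688). The strongest mutant-only regions lay 16.0 kb from Igsf10 (chromosome 3, 59359997 to 59360799), inside Prex2, a Rac exchange factor gene (chromosome 1, 11033186 to 11033971), and 38.7 kb from LOC115488002 (chromosome 12, 18609743 to 18610797). The others lay inside Efna5, an ephrin gene (chromosome 17, 62729599 to 62731077), and inside G3bp2, a gene of a stress granule protein (chromosome 5, 92128457 to 92129273). Lower percentiles of these 10 regions ran from 39.7 to 46.2 in the control-only set and from 55.7 to 63.9 in the mutant-only set.

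The ratio of 4.19 depended on the number of peaks taken from each list. With 22959 top-ranked peaks from each library there were 637 control-only and 710 mutant-only regions, a ratio of 1.11. In the upper 50% of each list there were 55 and 619 regions, a ratio of 11.3. With any 1 library left out, fewer libraries had to agree, and control-only regions numbered 983 to 3320 and mutant-only regions 2489 to 5532. The genotype left with 1 library gains regions by construction, and the ratio was 0.750 without control 2 and 4.93 without control 1. A missing call was also not shown to be a missing peak. Of 30359 gaps between neighbouring peaks of a list that held a region of other libraries, 100 had no gap in the peak numbers, against 34886 of 83783 gaps without such a region. Gaps with 1 region of the other 3 libraries held 1.60 more removed peaks (95% interval 1.43 to 1.77) than gaps of like length without one. All 4412 absences of control-only and mutant-only regions that lay between 2 listed peaks fell where at least 1 numbered peak had been removed, against 85.3% expected from gaps of like length without a region of other libraries.

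**Figure D2:**
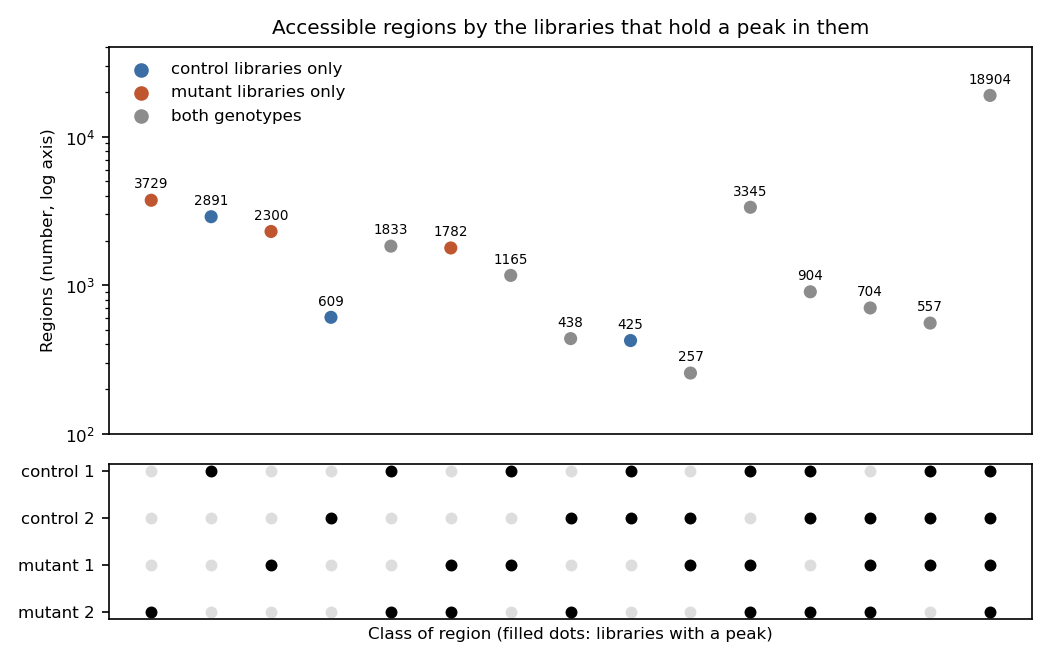
Number of regions (log axis) in each class of libraries, with filled dots under each point for the libraries that hold a peak. Regions in all 4 libraries number 18904, control-only regions 425 and mutant-only regions 1782.

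Regions found in exactly 2 libraries followed genotype more than the other pairings of the libraries. The yield-balanced ratio was 1.24 for genotype (95% interval 1.16 to 1.33), against 0.924 for the pairing by replicate number and 0.871 for the crossed pairing. Control-only regions were 1.35 times the 315 expected from library yields (1.19 to 1.53), and mutant-only regions 1.19 times the 1502 expected (1.11 to 1.26). With 3 pairings in all, the smallest exact p is 0.333, and the intervals cover the spread between chromosomes, not between embryos. At equal peak numbers the same-genotype classes held 1347 regions, against 1020 and 1077 in the other pairings. Over whole lists the Jaccard index was 0.624 and 0.654 within genotypes and ran from 0.603 to 0.652 between them, a difference of the means of 0.00709. The 3 lowest values, 0.603 to 0.624, were those of control 2, the shortest list. The difference of the means changed sign with the library left out. It was 0.0414 without control 1, 0.00280 without control 2, −0.00273 without mutant 1 and −0.0131 without mutant 2. Averaged over the 2 pairs of each pairing, so that every library counts once, the index was 0.639 for genotype, 0.627 by replicate number and 0.636 crossed, the highest of 3 (exact p = 0.333).

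**Figure D3:**
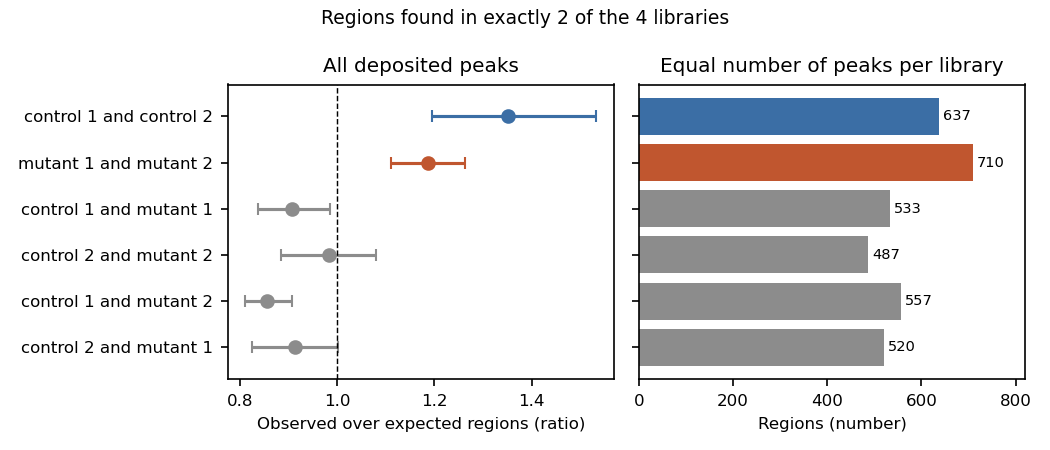
Left, observed over expected number of regions (ratio, with 95% intervals from resampled chromosomes) for the 6 classes of 2 libraries; right, number of regions in the same classes with equal numbers of peaks per library. The control pair stands at 1.35 and 637 regions and the mutant pair at 1.19 and 710.

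Regions found in exactly 2 libraries, genotype-specific or not, lay mostly away from gene ends and among the weaker peaks. Within 1 kb of a gene end were 50 of the 425 control-only regions (11.8%), 130 of the 1782 mutant-only regions (7.30%) and 9628 of the 18904 regions in all libraries (50.9%). In the 4 other classes of 2 libraries the share ran from 8.57% to 10.1%. Control-only regions exceeded mutant-only regions by 4.47 percentage points (95% interval 1.84 to 7.82, Fisher's exact p = 0.00403, adjusted p = 0.00672). By the same exact test this difference was −1.14 points without control 2 (p = 0.115) and 0.777 without control 1 (p = 0.476), and 8.49 without mutant 2; leaving out a library redefines both sets. In the upper 50% of each list it was 11.0 (exact p = 0.0738), and with equal peak numbers 8.01. The median lower percentile was 9.15 for control-only, 13.0 for mutant-only and 56.6 for regions in all libraries, and it ran from 8.24 to 12.5 in the 4 other classes of 2 libraries.

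None of the 22 gene lists held more of one kind of genotype-specific region than matched random lists (0 past the adjusted threshold, lowest adjusted permutation p = 0.639; 1 list at an unadjusted p under 0.05). Values below are control-only minus mutant-only regions per gene, relative to random lists. The interval given for anterior palate genes is the 95% range of random lists, from their SD, centred on the value. It covers the choice of genes and not the spread between libraries or embryos. Anterior palate genes had 1 control-only and 2 mutant-only regions (0.0551, interval −0.238 to 0.348), and posterior palate genes 0 and 1 (0.0534). The palate mesenchyme transcription factors had 4 of each (0.186, permutation p = 0.0617, adjusted p = 0.639). The heart and sinoatrial genes, a set named because Shox2 acts in the sinoatrial node, had 2 and 0, at Gata4 and Mef2c (0.242, permutation p = 0.0403, adjusted p = 0.639), and the value was −0.213 in the upper 50% of each list. The Mef2c region is also 1 of the 4 control-only regions of the palate mesenchyme transcription factors, so the values of these lists are not independent. Bone and cartilage lists had 0 control-only regions and 3 mutant-only regions each, with −0.0482 for osteogenic and −0.0808 for chondrogenic genes.

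Signalling lists were spread on both sides of their random lists. The BMP pathway had 0 control-only and 5 mutant-only regions (−0.0179), the FGF pathway 1 and 1 (0.163) and the hedgehog pathway 1 and 4 (−0.0109). The WNT pathway had 2 and 3 (0.133) and the TGF-beta pathway 2 and 1 (0.178). Extracellular matrix genes had 1 and 5 (−0.0572), limb and axial patterning genes 1 and 2 (0.0734), and axon guidance genes 2 and 9 (−0.0650). The ubiquitously used genes, a reference set, had 0 and 0 (0.0362).

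Markers of other cell types gave no list past the threshold either. Values were −0.158 for neuron, 0.186 for Schwann and glial, −0.133 for skeletal muscle, 0.0315 for endothelial, 0.154 for blood and immune, −0.0510 for epithelial and 0.199 for pericyte and smooth muscle markers. Skeletal muscle markers had 0 control-only and 2 mutant-only regions, at Pax3 and Ttn, and the value was 0.350 in the upper 50% of each list (adjusted permutation p = 0.187). The list passed the threshold when mutant 1 was left out (−0.652, adjusted permutation p = 0.00660), where mutant 2 alone, with 17 peaks at this list against 7 to 11 in the other libraries, stands for the mutants. Peaks at this list were 2.98 and 3.05 per 10000 in the controls and 3.76 and 5.34 in the mutants (exact permutation p = 0.333, the smallest the design allows). Those at the TGF-beta pathway were 19.2 and 20.04 against 16.8 and 17.0, and at the WNT pathway 31.8 and 30.5 against 27.0 and 29.2 (exact permutation p = 0.333 for both). In 8 of the 22 lists the exact permutation p of this measure was 0.333, which chance gives in 33.3% of lists.

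**Figure D4:**
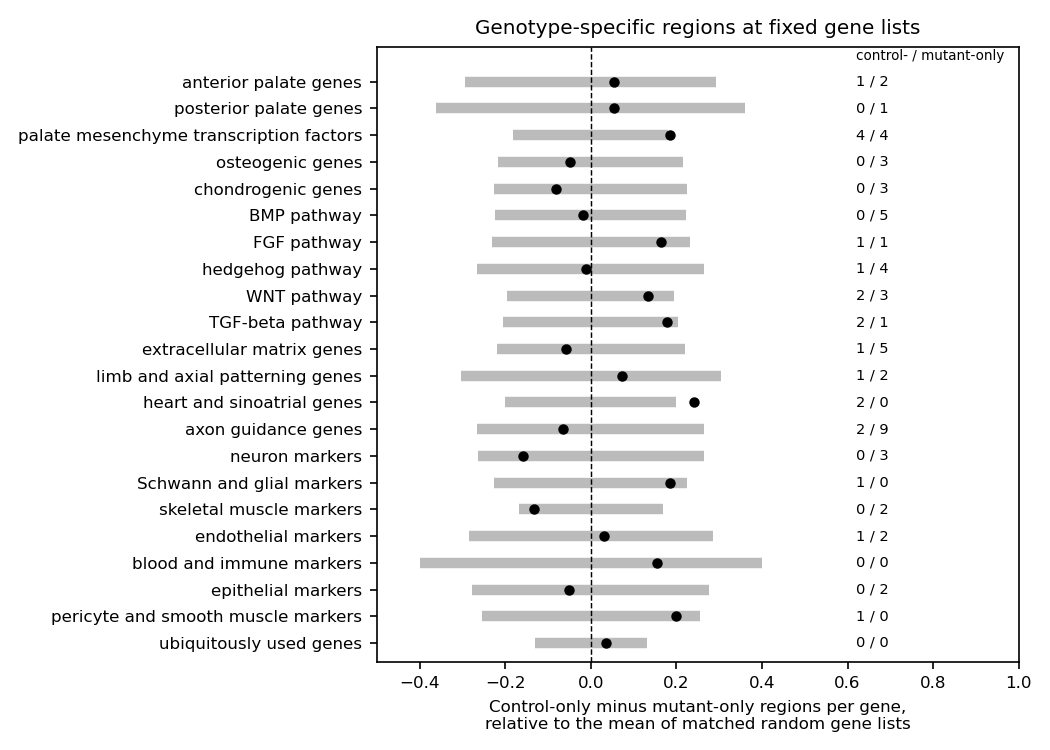
Control-only minus mutant-only regions per gene for the 22 lists (points), relative to the mean of matched random lists, with grey bars for the 95% range of the random lists from their SD and the counts of both kinds of region at the right. Before adjustment the heart and sinoatrial genes, at 0.242, lie beyond their bar. The palate mesenchyme transcription factors, at 0.186, lie at the edge of theirs. Neither list passes after adjustment, and both include the control-only region at Mef2c.

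Members of the lists held 18 control-only and 48 mutant-only regions, and 0 members differed by at least 2 regions. The examples that follow were chosen after their values were seen, and each is 1 region. Control-only regions lay at a gene end of Alx4 (chromosome 2, 93641669 to 93643192) and of Osr1 (chromosome 12, 9574267 to 9575015), both transcription factor genes of craniofacial mesenchyme, and 50.5 kb from Tbx3 (chromosome 5, 119619545 to 119620484). Osr1 also had a mutant-only region 60.5 kb away (chromosome 12, 9513431 to 9514475). A mutant-only region lay inside Runx2, a regulator of osteoblasts (chromosome 17, 44618106 to 44618861). Others lay inside Bmp2, a bone morphogenetic protein gene (chromosome 2, 133554220 to 133555062), inside Shh (chromosome 5, 28464465 to 28465396) and inside Ptch1, the hedgehog receptor gene (chromosome 13, 63525657 to 63526373). Lower percentiles were 11.9, 22.8 and 17.1 for the control-only regions of Alx4, Osr1 and Tbx3. For the mutant-only regions they were 14.6 at Osr1, 14.7 at Runx2, 5.16 at Bmp2, 3.13 at Shh and 26.0 at Ptch1.

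No single gene gathered enough genotype-specific regions for the planned test. The most at 1 gene was 4, so 0 genes reached the minimum of 5. None was tested at that minimum, and none is named by its Fisher p. At a minimum of 3, 27 genes were tested by Fisher's exact test, 0 passed after adjustment, and 0 had an unadjusted p under 0.05 (lowest p = 0.114). At these counts no gene could pass in the mutant direction, since 0 control-only and 4 mutant-only regions, the most seen, give an exact p of 0.585.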

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

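No result met the rules for a closer look on single values, and 3 patterns are weighed here. All tests of explanations below were chosen after the results were seen, except the comparison within strength quintiles; the equal-number setting itself was planned.

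Mutant-only regions outnumbered control-only regions 4.19 times. The imbalance did not lie on chromosomes X or 3, where the sex of a pool or the Shox2 alleles could act. Without them 391 control-only and 1625 mutant-only regions remained, a ratio of 4.16. Effects of sex or of the Shox2 alleles on regions of other chromosomes were not tested. With equal peak numbers the ratio was 1.11, so the shorter list of control 2 is a candidate explanation. The fit to library yields expected 315 control-only and 1502 mutant-only regions, an imbalance in the same direction and no smaller than the observed one. Observed counts were 1.35 times the expected for control-only regions (1.19 to 1.53) and 1.19 times for mutant-only regions (1.11 to 1.26). In the other pairings too the class with control 2 was the smaller, with 438 against 1165 and 257 against 1833 regions. A greater number of open regions in mutants was not tested apart from list length.

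Sharing of regions within a genotype exceeded sharing across genotypes, with a ratio of 1.24 against 0.924 as the highest other pairing. If the excess came only from DNA carried along with the Shox2 alleles on chromosome 3, leaving that chromosome out would give 1. The ratio was then 1.25 (1.16 to 1.34). DNA shared within a genotype on other chromosomes was not tested. Peaks of low rank as the only source would give a ratio of 1 among regions whose peaks all lie above percentile 25 of the full lists. There it was 1.64 (1.33 to 2.08), from 45 control-only and 356 mutant-only regions and 18 to 325 in the other classes. Calls missing from the other libraries depend on the unknown removal step, so a threshold effect on absences was not tested. The effect of Shox2 loss may account for the excess, as a hypothesis, but joint preparation of the libraries of a genotype, of which the labels say nothing, stays open as well. With 3 pairings no share under 0.05 can be had.

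Control-only regions lay near gene ends more often than mutant-only regions. A difference in peak strength between the sets would remove this within strength quintiles, where it was 4.64 points (1.94 to 8.05), which leaves −0.172 points to strength (−0.582 to 0.185, worked out later). If regions that include control 2 were the source, both other pairings would show it, and the smaller of their differences was −0.540 points (−3.75 to 3.05). The genotype difference exceeded theirs by 5.01 points (0.736 to 9.29) and 3.31 points (−0.0854 to 6.82), and the second interval includes 0. It was −1.14 without control 2 and 0.777 without control 1, but leaving out either control redefines both sets, so these values do not decide it and control 2 stays open as the source.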

How the results depend on the processing

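The yield-balanced ratio, the expected numbers, the regions in all 4 libraries, the exclusion of chromosome 3 and of chromosomes 3 and X, and the limit to regions above percentile 25 were chosen after the data were seen; other settings were planned. The motif alternatives were not run, and read depth, which limits every call, is unknown. The genotype ratio of 1.24 stayed between 1.23 and 1.28 under 5 alternatives and was 1.64 among regions whose peaks all lie above percentile 25 of the full lists. The cause of a change was not tested unless stated.

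In the upper 50% of each list there were 55 control-only and 619 mutant-only regions (ratio 11.3), with median percentiles of 53.7 and 54.4, which the narrower lists raise by construction, and the near-end difference was 11.0 points (Fisher's exact p = 0.0738). With equal peak numbers there were 710 mutant-only regions (ratio 1.11), and median percentiles were 16.1 and 31.3.

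With 1 library left out, control-only regions ranged from 983 to 3320 and mutant-only regions from 2489 to 5532, since fewer libraries had to agree, and their ratio from 0.750 to 5.63. The near-end difference ranged from −1.14 to 8.49 points, the within minus between Jaccard index from −0.0131 to 0.0414, the mutant-only median percentile from 12.9 to 19.8, and the number of lists past the threshold from 0 to 1.

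Of 264 list values under alternatives, 49 changed sign, with a lowest adjusted p of 0.187 among them, and 1 passed the threshold. With 1 library left out, values ranged from −0.0489 to 0.193 for the BMP pathway, −0.0383 to 0.301 for the FGF pathway, −0.252 to 0.0355 for the hedgehog pathway, −0.311 to 0.202 for anterior and −0.114 to 0.254 for posterior palate genes. They ranged from −0.0546 to 0.229 for palate mesenchyme transcription factors, −0.242 to 0.106 for osteogenic, −0.357 to 0.231 for chondrogenic, −0.640 to 0.234 for axon guidance, −0.275 to 0.113 for extracellular matrix and −0.179 to 0.521 for limb and axial patterning genes. Marker ranges were −0.0912 to 0.262 for blood and immune, −0.156 to 0.0945 for endothelial, −0.200 to 0.155 for epithelial and −0.531 to 0.0936 for neuron markers, and −0.103 to 0.145 for ubiquitously used genes.

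Signs also changed in the upper 50% for Schwann and glial (−0.171), blood and immune (−0.117), epithelial (0.0530) and skeletal muscle markers (0.350), the WNT pathway (−0.0608), extracellular matrix (0.00572) and heart and sinoatrial genes (−0.213). With equal numbers they changed for anterior palate (−0.0836), chondrogenic (0.00577) and ubiquitously used genes (−0.000713), and for endothelial (−0.00167), neuron (0.00598) and pericyte and smooth muscle markers (−0.102). On autosomes the hedgehog pathway stood at 0.00660. Within 1 Mb, anterior palate genes stood at −0.210, axon guidance genes at 0.0170 and the hedgehog pathway at 0.124. Within 20 kb, endothelial markers stood at −0.0340 and extracellular matrix genes at 0.0357. At 50% reciprocal overlap, axon guidance genes stood at 0.0404, the hedgehog pathway at 0.000169 and osteogenic genes at 0.0119.

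The labels do not say what a replicate number stands for, and the correlation of the deviations of same-numbered libraries was −0.00104, so the numbers were not used to pair them. The replicate block changed no call (0 lists by a Mantel-Haenszel chi-square test, lowest adjusted p = 0.503). Its log odds had the opposite sign for the BMP pathway (0.0602) and for anterior palate (−0.132), posterior palate (−0.198) and chondrogenic genes (0.259).

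For regions in all 4 libraries, the lists past the threshold numbered 4 within 20 kb and 6 in the upper 50%. Of 66 values, 13 crossed 1, with a lowest adjusted p of 0.395. Within 20 kb these were epithelial markers (0.701), extracellular matrix (0.934), heart and sinoatrial (0.838) and posterior palate genes (0.881). In the upper 50% they were blood and immune (0.513), epithelial (0.803) and neuron markers (1.10), and chondrogenic (0.612), heart and sinoatrial (0.701) and posterior palate genes (0.699). With equal numbers they were blood and immune (0.989) and epithelial markers (0.835) and posterior palate genes (0.828).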

Other observations

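The test of regions in all 4 libraries, with its other settings, was chosen after the data were seen.

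Some gene groups held many regions in every library, whatever the genotype. Axon guidance genes had 74 such regions at 21 of 22 members, 1.76 times the mean of random lists matched on territory (adjusted permutation p = 0.00440). Hedgehog pathway genes had 40 at 14 of 17 members, 1.92 times the mean (adjusted permutation p = 0.0110). The other 20 lists did not pass, among them the TGF-beta pathway at 1.61 times (adjusted permutation p = 0.0687), the palate mesenchyme transcription factors at 1.44 times (adjusted permutation p = 0.0653) and the ubiquitously used genes at 1.76 times (adjusted permutation p = 0.0823). Skeletal muscle markers had 4 such regions over 13 genes, 0.338 times the mean (adjusted permutation p = 0.124). Both calls held in the 3 other settings, within 20 kb, in the upper 50% of each list and with equal peak numbers (adjusted permutation p = 0.0308, 0.0205 and 0.00990 for axon guidance and 0.0308, 0.0205 and 0.00880 for hedgehog). Calls of other lists changed with the setting. The lists past the threshold numbered 2, against 4 with genes within 20 kb, 3 with equal peak numbers and 6 in the upper 50% of each list. The TGF-beta pathway passed in all 3 of these settings (adjusted permutation p = 0.0308, 0.0213 and 0.00660). The ubiquitously used genes, a reference set, passed within 20 kb and in the upper 50% (adjusted permutation p = 0.0379 and 0.0205). In the upper 50%, 2 of the 6 lists held fewer regions than random lists, limb and axial patterning genes at 0.245 times and skeletal muscle markers with 0 regions (adjusted permutation p = 0.0205 for both).

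Peaks on chromosome Y, outside the comparisons of the report, numbered 14 in control 1, 7 in control 2, 8 in mutant 1 and 11 in mutant 2. Regions at Eif2s3y, Uty and Ddx3y were held by all 4 libraries.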
